A study of Homo sapiens with 12 samples.

How the data were processed

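Small RNA and poly-A RNA of HEK293T cells transfected with a GFP control, a BCL2L11 trigger or a TRIM9 trigger plasmid were compared, with 2 libraries per group, 3 groups and 6 libraries per assay. Cells were transfected with PEI or lipofectamine, and which of these each sample received was not given in the sources used here. Replicate 1 of each group has title numbers 1 to 3 and replicate 2 has 4 to 6, called library sets 1 and 2. The labels state neither pairing nor batch, and the fits used groups only, with a term for the sets as an alternative. Gene levels differed between the sets in a similar way in each group, with correlations of 0.49 to 0.83 between the groups' deviations from their means. For miRNAs these correlations were 0.21 to 0.39. With the term 4991 of 15183 genes and 56 of 443 miRNAs passed for the sets, and more members of some lists passed for the triggers, as given with each result.

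Per the submitters' processing notes cutadapt 3.4, STAR, StringTie 2.1.3 and DESeq2 1.20.0 were used with the hg38 genome. The deposited count table gave reads per mature miRNA in each small RNA library, not normalised. The authors' deposited miRNA and isoform tables gave, per the file headers, the mean normalised signal over libraries (baseMean, in some also its log10), the log2 fold change, its standard error and a test statistic (a score), and the p-value with its adjusted value. The authors' deposited gene tables gave a fold change as a ratio, its log2, a p-value and a q-value for part of the genes. The tool and the filter behind them were not given in the sources used here. The deposited StringTie tables gave, per the file headers, the coverage signal (mean read depth per base) and the FPKM of each of 250719 transcripts per poly-A library, FPKM being a constant times coverage within each library. What the deposited isoform tables count was not given in the sources used here.

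Counts of miRNAs were fitted in edgeR 4.0.16 (TMM, filterByExpr, glmQLFit and glmQLFTest, group only, all 6 libraries in 1 fit), and 443 of 1153 miRNAs were tested. Gene FPKM was the sum over the transcripts of a gene, and log2 of FPKM plus 1 was fitted in limma 3.58.1 (trend, group only) for genes with FPKM of at least 1 in at least 2 libraries, 15183 of 67053. Of these, 994 lay off the assembled chromosomes and 1518 symbols had more than 1 locus. p was two-sided and adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05. An exact test of 2 against 2 libraries cannot go below p = 0.333, so the models that share the spread over all genes were used. Gene lists were tested by limma's camera with a preset correlation of 0.01 over 14 lists, and again with an estimated correlation and with fry, by which no list passed (lowest adjusted p 0.0552).

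Fixed before the data were examined were the tests, 17 gene lists, 6 miRNA lists, the settings to vary and the rule for the genes named. The gene lists were miR-221/222 targets, miR-218 targets, miRNA pathway factors, miRNA host genes, interferon response, unfolded protein response, heat shock response, BCL2 family and apoptosis, p53 targets, cell cycle, immediate early genes, cholesterol synthesis, mitochondrially encoded genes, replication-dependent histones, and fibroblast, blood and epithelial markers. The miRNA lists were passenger strands, the miR-17-92 family, the let-7 family, miRNAs with other published triggers, blood miRNAs, and muscle, liver and epithelial miRNAs. The rule named the triggered miRNAs and their passenger strands, BCL2L11, TRIM9 and the host genes, up to 10 miRNAs or 12 genes per direction that passed, otherwise the 5 of lowest p as not passing, up to 4 members of lowest p per list, and the 10 miRNAs of highest mean level. Fewer than 4 members are printed for some lists. Named outside it, after their values were seen, were miR-100-5p, miR-451a, miR-486-5p, miR-150-5p, miR-152-3p, HSPA8, ZSWIM8, MDM2 as a p53 target, CDKN1B as a target, RN7SK and the RNAs and genes of the closing tests.

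The settings varied for miRNAs were size factors of DESeq2, total counts, no filter, at least 100 counts in 2 libraries, DESeq2 1.42.0, a fit of the compared groups alone, a term for the library sets, the libraries of the other trigger as control and leaving out each library. For genes they were FPKM rescaled by TMM, a pseudocount of 0.1, an FPKM filter of 5, no filter, no trend, the compared groups alone, the library sets, leaving out each library and, for lists, the estimated correlation. Chosen after the data were seen were the assembled chromosomes only, list tests with TMM, with the library sets, without each library and without BCL2L11, and the ratio of the miR-221 strands.

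The fits by edgeR and limma and the camera tests were tested on simulated data for the comparisons with GFP. DESeq2, fry, the fits with a term for the library sets and the direct comparison of the triggers were not. Genes were simulated as independent of each other, so false list calls from correlated genes were not tested. For BCL2L11 and TRIM9 against GFP edgeR recovered 5% and 25% of 20 miRNAs changed 1.5-fold, 65% and 65% of those changed 2-fold and 100% and 100% of those changed 4-fold, with 2 and 1 false calls, and limma 1% and 1% of 100 genes changed 2-fold and 57% and 55% of those changed 4-fold, with 3 and 4 false calls. Camera recovered 20 of 20 lists of 14 genes lowered by 0.5 with the preset correlation and 0 of 20 with the estimated one. For a list of independent genes, not passing with the estimated correlation therefore does not argue against the list. The simulation cannot decide this for lists of correlated genes. The estimated correlation was 0.70 for immediate early, 0.37 for mitochondrially encoded and 0.15 for histone genes. It was 0.05 for p53 targets and 0.02 for heat shock genes.

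Library totals were 5232640 and 5266563 miRNA reads for GFP, 5018875 and 6091151 for BCL2L11 and 5304356 and 5361685 for TRIM9. Seed sites in 3′ untranslated regions were not analysed here, as no genome sequence was used, nor were isoforms per library. miR-218-2-3p was not listed in the table used, and SLIT3 was below the filter. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, with figures drawn in matplotlib 3.10.9.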

Results

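HEK293T, a human embryonic kidney cell line that expresses the large T antigen, was transfected with a plasmid whose GFP reporter carried in its 3′ untranslated region either no added trigger (GFP control), a stretch of BCL2L11, or a stretch of TRIM9. Each stretch is a trigger of target-directed microRNA degradation, in which extensive pairing between a target RNA and a microRNA (miRNA) leads to loss of the miRNA. The question was whether the BCL2L11 trigger lowered miR-221 and miR-222 and the TRIM9 trigger lowered miR-218. RNA was taken 48 h after transfection with 2 µg of plasmid. Small RNA of 18 to 40 nt and poly-A RNA were each sequenced from 2 libraries per group, given as biological replicates, which makes 12 libraries in all. Small RNA libraries held 5018875 to 6091151 reads assigned to miRNAs, and poly-A libraries held 83584 to 110534 transcripts with FPKM above 0. No pair among the 15 pairs of libraries of either assay held identical values (0 of 15 each).

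In all 6 small RNA libraries miR-148a-3p held the largest share of the reads, 57.7% to 67.2%, and miR-7-5p, the miRNA removed in brain by the RNA Cyrano, followed with 12.9% to 16.2%. The next in mean level were miR-10a-5p, miR-151a-3p, miR-218-5p, miR-92a-3p, miR-25-3p, miR-21-5p, miR-10b-5p and miR-30d-5p. Among the miRNAs the triggers pair with, miR-221-3p had 9830 to 30409 reads per library, miR-222-3p 13556 to 29722 and miR-218-5p 53775 to 116350. Of 1153 miRNAs listed, 443 passed the filter and were tested.

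With the BCL2L11 trigger, miR-221-3p fell by 55.2% against GFP (log2 fold change -1.16, SE 0.15, n = 2 libraries per group, adjusted p = 0.0258 in edgeR). Its counts were 9830 and 10985 against 21969 and 24989 in GFP cells. Its cluster partner miR-222-3p, which shares its seed, stood at 0.663 of the GFP level (log2 fold change -0.59, SE 0.18). The adjusted p of miR-222-3p was 0.995 over all miRNAs tested and 0.0162 adjusted over the list alone of the 3 miRNAs the study named. On that list miR-221-3p had an adjusted p of 1.75e-04, and miR-218-5p, which the BCL2L11 trigger does not pair with, had a log2 fold change of 0.16 (SE 0.14) and 0.289. The log2 differences within library set 1 (title numbers 1 to 3) and set 2 (title numbers 4 to 6) were -1.13 and -1.18 for miR-221-3p and -0.65 and -0.55 for miR-222-3p. The call of miR-221-3p over all miRNAs was kept with DESeq2 (adjusted p = 5.62e-06) and with a term for the library sets in edgeR (8.77e-06). In edgeR it was also kept with no filter (7.93e-06), at least 100 counts in 2 libraries (0.0153) and size factors of DESeq2 (0.04255). The call ended when total counts replaced TMM (adjusted p = 0.356) and when only the GFP and BCL2L11 libraries were fitted (0.0878). It also ended without GFP replicate 1 (0.193), GFP replicate 2 (0.477), BCL2L11 replicate 1 (1.0), BCL2L11 replicate 2 (0.468), TRIM9 replicate 1 (0.083) or TRIM9 replicate 2 (0.0733), while the log2 fold change stayed between -1.25 and -1.07. Its adjusted p over the list alone was highest without BCL2L11 replicate 1 (0.0066). With a term for the library sets miR-222-3p also passed over all miRNAs (adjusted p = 0.019, range over its alternatives 0.019 to 1.0). Over the list alone it did not pass without BCL2L11 replicate 1 (0.174) or GFP replicate 2 (0.121).

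**Figure D1:**
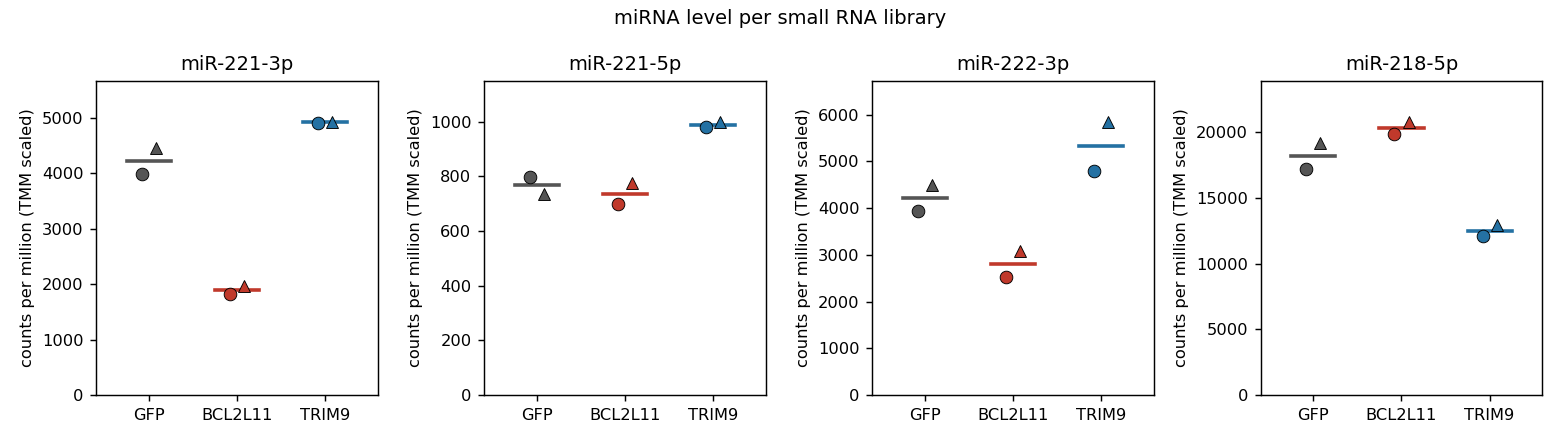
Reads scaled by library size and TMM factors (CPM) of miR-221-3p, miR-221-5p, miR-222-3p and miR-218-5p in each small RNA library; circles are replicate 1, triangles replicate 2 and lines the mean of the group. miR-221-3p stood at 1828 and 1961 with the BCL2L11 trigger against 3992 and 4458 in GFP cells, and miR-218-5p at 12096 and 12899 with the TRIM9 trigger against 17195 and 19179.

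The opposite strand of the miR-221 hairpin, miR-221-5p, had a log2 fold change of -0.06 (SE 0.16) with the BCL2L11 trigger, with 3763 and 4338 reads against 4395 and 4125. The ratio of miR-221-3p to miR-221-5p reads, which needs no scaling between libraries, was 2.61 and 2.53 with this trigger, 5.00 and 6.06 in GFP cells, and 5.01 and 4.93 with the TRIM9 trigger. The passenger strands miR-222-5p (10 to 36 reads) and miR-218-1-3p (9 to 17 reads) had log2 fold changes of 0.18 (SE 0.54) and -0.31 (SE 0.54), and at this depth no difference was detectable. None of the 3 passenger strands tested passed, over all miRNAs or adjusted over the list alone (0 and 0).

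No miRNA other than miR-221-3p passed in the BCL2L11 comparison: edgeR and DESeq2 each called 1 of 443, with 6 and 4 below an unadjusted p of 0.05. The other miRNAs of lowest p were miR-215-5p (log2 fold change 0.70, SE 0.22), miR-580-3p (-1.28, SE 0.41, 12 to 34 reads) and miR-188-5p (1.17, SE 0.44). With a term for the library sets 5 miRNAs passed, namely miR-221-3p, miR-222-3p, miR-215-5p, miR-100-5p (-1.02, adjusted p = 0.017) and miR-451a (-1.23, adjusted p = 0.0404), the last a miRNA of red blood cells with 2324 reads in BCL2L11 replicate 1 and 11951 in replicate 2. The replicates of miR-100-5p also differed, at 32.35 and 78.56 CPM with the BCL2L11 trigger against 95.40 and 112.74 in GFP cells. Of the blood miRNAs 2 were tested, miR-451a and miR-486-5p (-0.77 and -0.38), and of the muscle, liver and epithelial miRNAs 6 (median -0.27), with 0 calls over all or adjusted over the list alone. Of the most abundant miRNAs miR-148a-3p stood at 0.15 (SE 0.24) and miR-7-5p at 0.03 (SE 0.18), and none of the 10 passed. Of the miR-17-92 family (10 tested), the let-7 family (9) and the miRNAs with other published triggers (9, among them miR-7-5p and miR-29b-3p), 0 members passed over all miRNAs and 0 adjusted over the list alone, with medians of -0.11, 0.04 and 0.03.

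With the TRIM9 trigger, miR-218-5p stood at 0.687 of the GFP level (log2 fold change -0.54, SE 0.14, n = 2 libraries per group), with 74814 and 53775 reads against 94621 and 107515. Its adjusted p was 0.958 over all miRNAs and 0.0143 adjusted over the list alone of the 3 named miRNAs. On the same list miR-221-3p and miR-222-3p had log2 fold changes of 0.22 (SE 0.15) and 0.33 (SE 0.18) and adjusted p of 0.176 and 0.148. These were 0.093 and 0.0239 with a term for the library sets, so that miR-222-3p, which the TRIM9 trigger does not pair with, passed on the higher side over the list alone. Over all miRNAs the adjusted p of miR-222-3p ranged from 0.392 to 0.999 over its alternatives. The log2 differences of miR-218-5p were -0.51 in library set 1 and -0.57 in set 2, and with a term for the sets its adjusted p was 0.162 over all miRNAs and 0.0011 adjusted over the list alone. Over its alternatives against GFP the adjusted p over all miRNAs ranged from 0.162 to 0.999, and it was 0.158 with the BCL2L11 libraries as control. Adjusted over the list alone, miR-218-5p passed in 5 of 6 fits that left out 1 library, and did not without GFP replicate 2 (adjusted p = 0.127, log2 fold change between -0.64 and -0.49 over the 6 fits).

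In the TRIM9 comparison edgeR called 0 of 443 miRNAs over all, DESeq2 0 and the fit with a term for the library sets 0, with 20, 9 and 35 below an unadjusted p of 0.05. Without the filter edgeR called 1, miR-150-5p (6.86, adjusted p = 3.51e-14), whose reads lay in TRIM9 replicate 1 alone (158, against 2 in replicate 2 and 0 and 1 in GFP cells). The miRNAs of lowest p besides miR-218-5p were miR-122-5p, the main miRNA of liver (log2 fold change 1.48, SE 0.39, 92 and 40 reads against 28 and 21), miR-552-3p (-3.47, SE 1.01, 0 to 14 reads), miR-193a-5p (1.04, SE 0.34) and miR-190b-5p (-1.24, SE 0.41). Of the 6 muscle, liver and epithelial miRNAs tested, 0 passed over all miRNAs and 1, miR-122-5p, adjusted over the list alone. Of the blood miRNAs 2 were tested, miR-451a (-0.27) and miR-486-5p (-0.15), with 0 calls over all or adjusted over the list alone. The passenger strands gave 0 and 0 calls (miR-221-5p 0.37, SE 0.16, miR-222-5p with 32 and 36 reads against 10 and 23, miR-218-1-3p -0.09, SE 0.54), as did the miR-17-92 family (median -0.16), the let-7 family (-0.01) and the miRNAs with other published triggers (0.03).

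**Figure D2:**
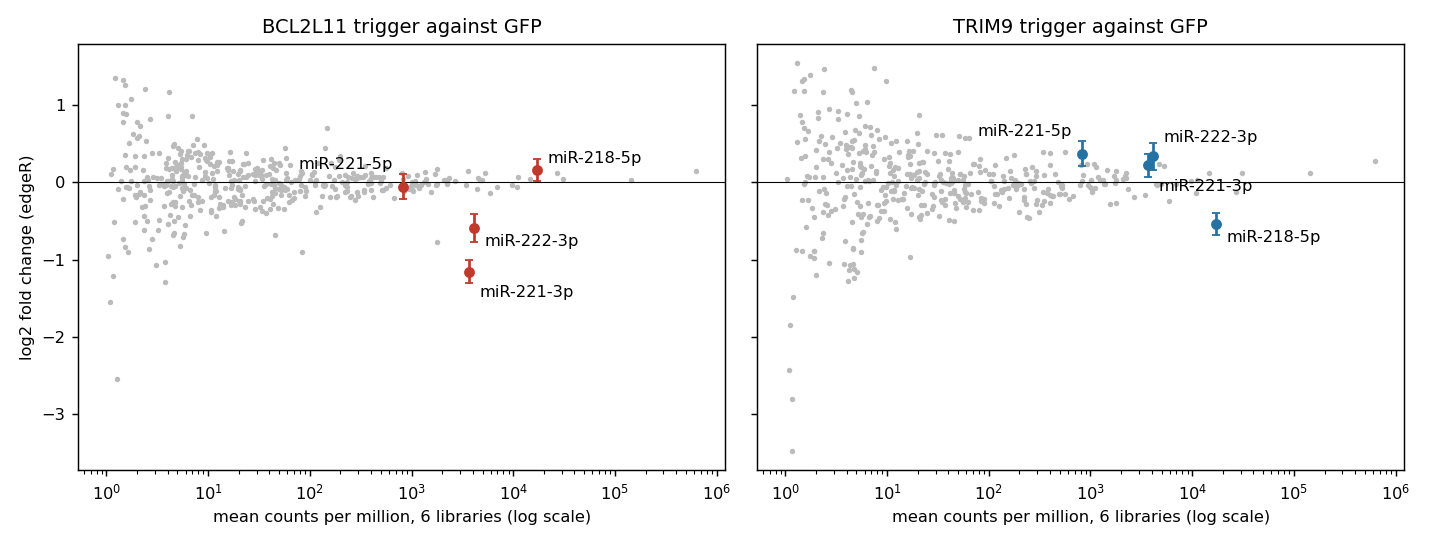
Log2 fold change from edgeR of the 443 miRNAs tested (grey points) against their mean CPM over the 6 small RNA libraries on a log scale, for each trigger against GFP; coloured points with SE bars are the miRNAs named. miR-221-3p stood at -1.16 and miR-222-3p at -0.59 with the BCL2L11 trigger, and miR-218-5p at -0.54 with the TRIM9 trigger.

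Set directly against each other, which uses none of the shared GFP libraries as a control, the triggers separated all 3 miRNAs in opposite directions. miR-221-3p fell by 61.5% in BCL2L11 against TRIM9 cells (log2 fold change -1.38, SE 0.15, adjusted p = 0.0076 in edgeR, within-set log2 differences -1.43 and -1.33). miR-222-3p had a log2 fold change of -0.93 (SE 0.18) and miR-218-5p one of 0.70 (SE 0.14), each with an adjusted p of 0.158 over all miRNAs and 0.00107 adjusted over the list alone. DESeq2 called the 3 miRNAs over all miRNAs (3 calls against 1 in edgeR, with 10 and 12 below an unadjusted p of 0.05), with adjusted p of 5.91e-09, 0.0286 and 0.0452. The fit with a term for the library sets called 4 (39 below an unadjusted p of 0.05), these and miR-152-3p (0.65, adjusted p = 0.0455). Over its alternatives the adjusted p ranged from 5.91e-09 to 0.434 for miR-221-3p, 1.07e-04 to 0.995 for miR-222-3p and 0.00306 to 0.869 for miR-218-5p. The edgeR call of miR-221-3p was not made with total counts in place of TMM, in a fit of these groups alone, or without BCL2L11 replicate 1, BCL2L11 replicate 2 or TRIM9 replicate 1 (0 calls in each). Without TRIM9 replicate 2 there were 2 calls, the other being miR-150-5p. The passenger strands, the miR-17-92 and let-7 families (medians 0.05 and 0.06) and the miRNAs with other published triggers (-0.02) gave 0 calls over all and 0 adjusted over the list alone. miR-221-5p stood at -0.43 (SE 0.16), miR-122-5p at -1.10 (SE 0.38) and miR-3615 at 0.51 (SE 0.18). The remaining lists, of blood (2 tested) and of muscle, liver and epithelial miRNAs (6 tested), gave 0 and 0 calls with medians of -0.37 and -0.48.

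The authors' deposited tables of miRNA counts held 1 miRNA below an adjusted p of 0.05 for BCL2L11 (4 at an unadjusted p under 0.05) and 0 for TRIM9 (10). The authors' deposited gene tables held 0 and 0 below a q-value of 0.05 (209 and 152 at an unadjusted p under 0.05). In the authors' deposited table for BCL2L11 miR-221-3p had a log2 fold change of -1.15 (SE 0.21, adjusted p = 3.69e-05) and miR-222-3p one of -0.58 (adjusted p = 0.999), and in that for TRIM9 miR-218-5p had -0.54 (adjusted p = 0.997). The authors' deposited tables of miRNA isoforms held positive values for the same 3 miRNAs. The mean normalised signal of miR-221-3p, miR-222-3p and miR-218-5p there was 344, 570 and 939. In the authors' tables of miRNA counts it was 19371, 21697 and 89664. For BCL2L11 miR-221-3p stood at 1.67 (SE 0.12, adjusted p = 2.84e-39) and miR-222-3p at 1.07 (SE 0.09, adjusted p = 1.76e-32), the 2 entries of 1328 that passed in the authors' deposited table. For TRIM9 miR-218-5p stood at 2.55 (SE 0.08, adjusted p = 5.77e-247), the 1 entry of 1329 that passed in the authors' deposited table. Which reads were counted as isoforms was not given in the sources used here, and isoform counts per library were not analysed here.

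In the poly-A libraries the most changed genes were those the triggers came from. BCL2L11, which encodes the pro-apoptotic protein BIM (chromosome 2, 111119378 to 111168445, plus strand, hg38), rose from 5.40 and 6.15 FPKM in GFP cells to 11484 and 11275 with its trigger (log2 fold change 10.72, SE 0.32, n = 2 per group, adjusted p = 6.92e-05 in limma). TRIM9, a ubiquitin ligase of neurons (chromosome 14, 50975262 to 51096061, minus strand), rose from 1.74 and 2.92 FPKM to 5297 and 3948 with its own (10.45, SE 0.36, adjusted p = 1.84e-04). Reads of the plasmid's trigger are counted in these values, so they do not measure the cells' own BCL2L11 or TRIM9 transcripts. With the other trigger BCL2L11 stood at 3.95 and 6.32 FPKM and TRIM9 at 1.21 and 2.30. Of 15183 genes tested limma called 1 for each trigger against GFP, BCL2L11 and TRIM9 themselves, with 83 and 175 genes below an unadjusted p of 0.05.

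Beyond its own gene, the BCL2L11 trigger gave small list differences that did not hold across settings. Histone genes made in S phase were lower as a list (camera, adjusted p = 0.0193, adjusted p = 0.903 with an estimated correlation), with H3C2 at -1.07 (SE 0.31) and H4C3 at -0.78 (SE 0.49). Immediate early genes were lower (adjusted p = 0.0382, adjusted p = 0.903 with an estimated correlation), led by the phosphatase gene DUSP1 (-0.84, SE 0.28) and the stress transcription factor gene ATF3 (-0.71, SE 0.29). Mitochondrially encoded genes were higher (adjusted p = 0.0252, adjusted p = 0.903 with an estimated correlation), led by MT-ND3 (0.54, SE 0.49). The BCL2 family and apoptosis list was higher (adjusted p = 0.0193, adjusted p = 0.876 with an estimated correlation), but not without BCL2L11 itself (0.549, range over its alternatives 0.0275 to 0.876), and its other named members BBC3 (0.69, SE 0.59), BAK1 (0.43, SE 0.39) and HRK (-0.34, SE 0.31) went both ways. No member of these lists passed over all 15183 genes or adjusted over the list alone except BCL2L11 (1 and 1 in its list, 0 and 0 in the others). Once a term for the library sets was fitted, 2 immediate early genes and 1 histone gene passed adjusted over the list alone, and 0 of these over all genes. Within the library sets DUSP1 stood at -0.77 and -0.91, ATF3 at -0.63 and -0.79, H3C2 at -1.16 and -0.97, and MT-ND3 at 1.14 and -0.05. The histone call ended without GFP replicate 1 (0.674) or BCL2L11 replicate 2 (0.847), and the BCL2 family call without GFP replicate 1 (0.127), GFP replicate 2 (0.0683) or BCL2L11 replicate 2 (0.0584). Of the fits that left out 1 library, the call of the mitochondrial genes was kept only in that without GFP replicate 2 (0.00847), and ended without GFP replicate 1 (0.815), BCL2L11 replicate 1 (0.0514), BCL2L11 replicate 2 (0.628), TRIM9 replicate 1 (0.071) or TRIM9 replicate 2 (0.0722). That of the immediate early genes was kept only without GFP replicate 1 (9.40e-06). It ended without BCL2L11 replicate 1 (0.474), BCL2L11 replicate 2 (0.18), TRIM9 replicate 1 (0.071) or TRIM9 replicate 2 (0.0722), and turned to the higher side without GFP replicate 2 (0.631). With a term for the library sets the histone (0.0688), BCL2 family (0.0688) and immediate early (0.103) calls ended and that of the mitochondrial genes was kept (0.00795). Yet of the 13 mitochondrial genes only 1 was higher in both library sets, and 1 was lower in both. The calls that ended with TMM-rescaled FPKM were those of the immediate early (0.053) and mitochondrial (0.0534) genes.

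The genes of lowest p besides BCL2L11, none of which passed, were RAB4B-EGLN2 (log2 fold change 2.12, SE 0.37), AC025165.3 (2.06, SE 0.37), AL671762.1 (1.98, SE 0.39) and ANKRD26P1 (0.98, SE 0.24) among the higher ones. On the lower side stood GEMIN7-AS1 (-1.84, SE 0.46), FERMT3, the gene of the integrin activator kindlin-3 (-1.46, SE 0.39), AC112715.1 (-1.12, SE 0.31) and MIR3662 (-1.28, SE 0.38). RAB4B-EGLN2, AC025165.3 and AL671762.1 overlap other genes on their strand, and the summed FPKM of each overlap differed from GFP by 0.36 (SE 0.47), -0.02 (SE 0.31) and -0.05 (SE 0.39) on the log2 scale.

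With the TRIM9 trigger, genes of the heat shock response were lower as a group (camera, adjusted p = 9.40e-08, adjusted p = 0.103 with an estimated correlation, median log2 fold change -0.36 against -0.04 for the other genes). The inducible HSP70 gene HSPA6 stood at 29.6 and 23.5 FPKM against 274 and 241 in GFP cells (log2 fold change -3.24, SE 0.36). The co-chaperone genes DNAJB1 (-1.71, SE 0.32) and BAG3 (-1.23, SE 0.29) and the HSP70 gene HSPA1B (-1.15, SE 0.39) followed. None of the 14 members passed over all genes in limma (0, HSPA6 adjusted p = 0.122) and 3 did adjusted over the list alone, HSPA6, DNAJB1 and BAG3 (4 with a term for the library sets). In both library sets 10 of 14 members were lower, with HSPA6 at -3.17 and -3.30, DNAJB1 at -1.72 and -1.70, BAG3 at -0.96 and -1.51 and HSPA1B at -0.89 and -1.42. The constitutive chaperone gene HSPA8, chosen after its value was seen, stood at -0.06 (SE 0.36). Summed over all their loci, the near-identical HSPA1A and HSPA1B stood at -1.15 (SE 0.40) and HSPA6 with its copy HSPA7 at -3.24 (SE 0.35). With a term for the library sets HSPA6 passed over all genes (adjusted p = 0.0360), and with only the GFP and TRIM9 libraries fitted it passed as well (adjusted p = 0.00774, range over its alternatives 0.00774 to 1.0). It also passed without BCL2L11 replicate 1 (0.00823) or BCL2L11 replicate 2 (0.00915), each of which gave 5 gene calls.

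**Figure D3:**
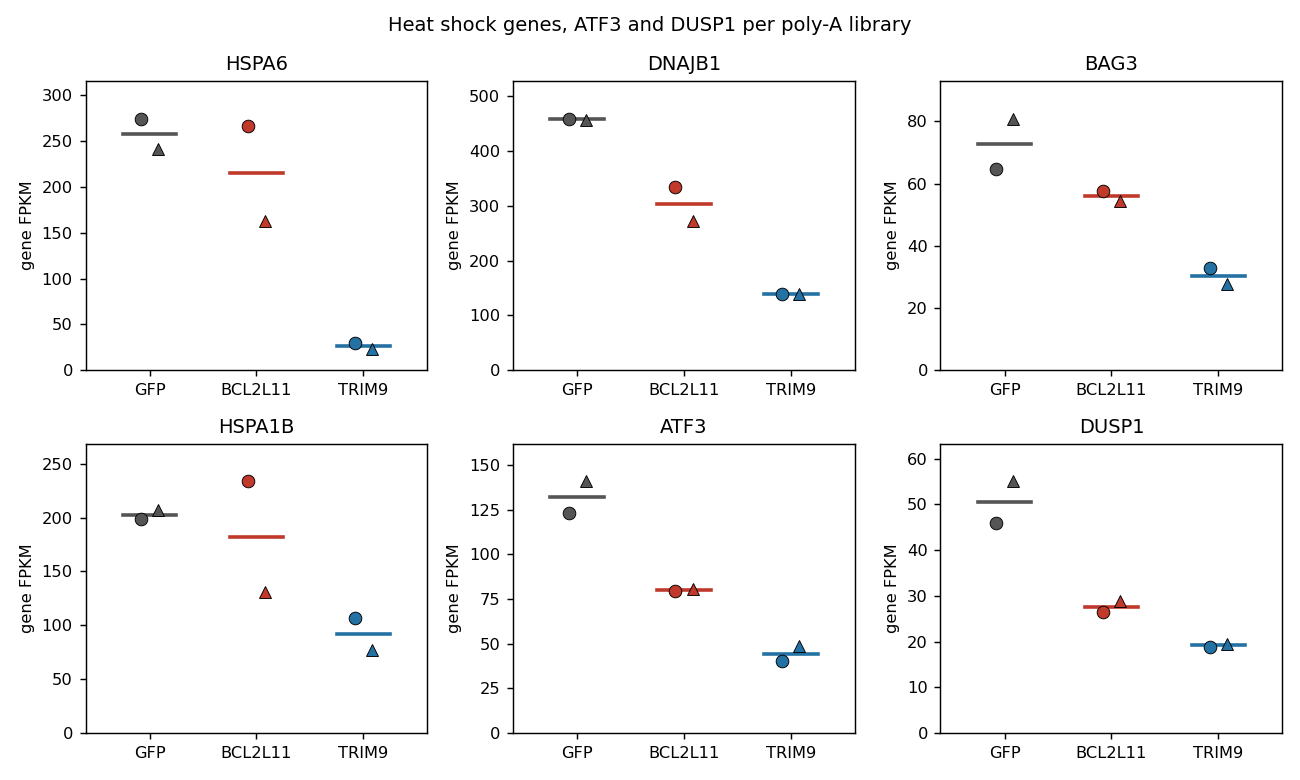
Gene FPKM of HSPA6, DNAJB1, BAG3, HSPA1B, ATF3 and DUSP1 in each poly-A library; circles are replicate 1, triangles replicate 2 and lines the mean of the group. DNAJB1 stood at 139 and 139 with the TRIM9 trigger, 333 and 272 with the BCL2L11 trigger and 458 and 456 in GFP cells.

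Targets of p53 were lower as a group with the TRIM9 trigger (adjusted p = 1.61e-07, adjusted p = 0.103 with an estimated correlation, median -0.43). In both library sets 14 of 18 were lower, among them the antiproliferative gene BTG2 (-0.99, SE 0.28, within sets -1.04 and -0.93), the DNA repair gene DDB2 (-0.99, SE 0.38, -0.76 and -1.22), the nuclease gene AEN (-0.69, SE 0.29, -0.53 and -0.86) and MDM2, which encodes the ligase that degrades p53 (-0.64, SE 0.43, -0.81 and -0.47). None of the 18 passed over all genes or adjusted over the list alone (0 and 0), while with a term for the library sets 5 passed over the list alone and 0 over all genes. The activity of p53 itself was not measured, so the list does not show a change in it. Replication-dependent histone genes were lower too (adjusted p = 6.50e-10, adjusted p = 0.103 with an estimated correlation, median -0.75), 9 of 10 in both sets. H3C2 (-1.31, SE 0.31) and H1-4 (-1.18, SE 0.33) passed adjusted over the list alone (2 of 10, and 6 with a term for the library sets) and 0 passed over all genes in either fit. These mRNAs mostly lack a poly-A tail. Of 6 other RNAs without one, chosen after their values were seen, RN7SK stood at 16.6 and 7.11 FPKM against 202 and 70.0 in GFP cells (-3.33, SE 0.80), RMRP at -2.30 (SE 1.05), RPPH1 at -1.80 (SE 0.49) and SNORD3A at -0.61 (SE 0.67), but RN7SL1 at 0.49 (SE 1.09) and RN7SL2 at 0.74 (SE 1.24). RN7SK did not pass over all genes in limma (adjusted p = 1.0) and was 1 of the 6 genes that passed with a term for the library sets (SE 0.26, adjusted p = 0.0499).

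The unfolded protein response list was lower with the TRIM9 trigger (adjusted p = 0.0217, adjusted p = 0.218 with an estimated correlation), with ATF3 at -1.55 (SE 0.29, within sets -1.59 and -1.52), DDIT3 at -0.67 (SE 0.36) and CHAC1 at 0.62 (SE 0.36). Only ATF3 of its 20 members passed adjusted over the list alone (1) and 0 passed over all genes, and the list's call ended without GFP replicate 1 (0.0792), GFP replicate 2 (0.159) or TRIM9 replicate 2 (0.305). Mitochondrially encoded genes were higher (adjusted p = 0.00167, adjusted p = 0.590 with an estimated correlation), 12 of 13 above 0 with MT-CO3 at 0.65 (SE 0.52) and MT-ND2 at 0.57 (SE 0.48), 0 calls over all or adjusted over the list alone, and no call of the list without GFP replicate 1 (0.231) or TRIM9 replicate 2 (0.305). Immediate early genes did not pass as a list (adjusted p = 0.164), but ATF3 and DUSP1 (-1.35, SE 0.28, within sets -1.24 and -1.46) passed adjusted over the list alone (2 of 13, 0 over all genes), while JUNB stood at 0.80 (SE 0.40). Without GFP replicate 1 the list passed on the lower side (1.01e-04).

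Among single genes in the TRIM9 comparison, RAB4B-EGLN2 (3.68, SE 0.37), AC025165.3 (3.36, SE 0.37) and HSPA7 (-2.76, SE 0.30) each had an adjusted p of 0.122 and passed with a term for the library sets (adjusted p = 0.0499 each, ranges over their alternatives 0.00774 to 1.0, 0.00774 to 1.0 and 0.0351 to 1.0). The summed FPKM of the genes that overlap on the strand differed by 0.12 (SE 0.47) at RAB4B-EGLN2 and by 0.11 (SE 0.31) at AC025165.3. FERMT3 (-2.37, SE 0.39), the cytokine gene IL17F (-1.72, SE 0.28), AC107959.2 (-1.72, SE 0.27), MSX2P1 (1.32, SE 0.26) and POLR2KP1 (1.07, SE 0.26) did not pass, with FERMT3 at 1.96 and 0.958 FPKM against 11.3 and 11.6.

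The direct comparison of the triggers gave 2 gene calls in limma, BCL2L11 (log2 fold change 10.88, SE 0.32, adjusted p = 6.20e-05) and TRIM9 (-10.73, SE 0.36, adjusted p = 7.65e-05), with 98 genes (0.645%) below an unadjusted p of 0.05. This share too lies below the 0.05 expected if no gene differed. Heat shock genes were higher in BCL2L11 than in TRIM9 cells (adjusted p = 1.97e-12, adjusted p = 0.0795 with an estimated correlation), with HSPA6 at 2.94 (SE 0.36, within sets 3.13 and 2.74), DNAJB1 at 1.11 (SE 0.32) and BAG3 at 0.87 (SE 0.29). HSPA6 passed adjusted over the list alone (1 of 14, 0 over all genes, adjusted p = 0.214). It passed over all genes with a term for the library sets (adjusted p = 0.0414, range over its alternatives 0.0414 to 1.0), and 4 of 14 passed adjusted over the list alone. Targets of p53 were higher (adjusted p = 1.16e-09, adjusted p = 0.103 with an estimated correlation), with BTG2 at 0.87 (SE 0.28), GDF15 at 0.59 (SE 0.32) and DDB2 at 0.68 (SE 0.38). Histone genes were higher (adjusted p = 7.49e-08, adjusted p = 0.135 with an estimated correlation), with H2AC18 at 0.93 (SE 0.40) and H1-4 at 0.70 (SE 0.33), though not without BCL2L11 replicate 1 (0.0866). The unfolded protein response list was higher (adjusted p = 0.00862, adjusted p = 0.135 with an estimated correlation) with ATF3 at 0.84 (SE 0.29), and the call ended without BCL2L11 replicate 1 (0.19), BCL2L11 replicate 2 (0.133), TRIM9 replicate 1 (0.0989) or TRIM9 replicate 2 (0.304). The BCL2 family list was higher (adjusted p = 0.00123, adjusted p = 0.135 with an estimated correlation) and not without BCL2L11 itself (0.213) or without TRIM9 replicate 1 (0.0668). These lists gave 0 and 0 member calls over all genes and adjusted over the list alone, BCL2L11 and HSPA6 aside, and with a term for the library sets 1 p53 target also passed over the list alone.

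AL671762.1 (3.38, SE 0.39), HSPA7 (2.51, SE 0.30) and AC125257.1 (2.54, SE 0.39) were the other genes of lowest p on the higher side of this comparison, and AL162411.1 (-1.23, SE 0.29), MSX2P1 (-1.31, SE 0.26), RAB4B-EGLN2 (-1.56, SE 0.37) and RUBCNL (-0.96, SE 0.27) on the lower side. None of these passed.

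Published targets of miR-221/222 and of miR-218 did not pass as lists. For miR-221/222 targets (34 tested) the adjusted p was 0.553 with the BCL2L11 trigger and 0.951 without BCL2L11 itself. The median was -0.12 while the mean was 0.24 and the test pointed up. Without BCL2L11 the median was -0.13 and the test pointed down. The cell cycle inhibitor gene CDKN1B, a well known target, stood at 0.31 (SE 0.33, 24.5 and 36.0 FPKM against 20.8 and 27.1), and in BCL2L11 against TRIM9 cells at 0.66 (SE 0.33). Leaving out BCL2L11 replicate 1 gave that list an adjusted p of 1.07e-04 with the test pointing up and BCL2L11 kept in the list. With all libraries 23 of 34 stood below 0, but the median of the other genes was also below 0 (-0.08). That number is therefore not evidence of a fall of the targets. The members of lowest p after BCL2L11 were TCEAL1 (-0.52, SE 0.34), PPP2R2A (-0.39, SE 0.31) and RNF20 (-0.35, SE 0.30). For miR-218 targets (29 tested) with the TRIM9 trigger the adjusted p was 0.586, with 17 of 29 below 0 and a median of -0.04 for the other genes. NACC1 stood at 0.57 (SE 0.46, within sets 1.49 and -0.34), the cell cycle gene E2F2 at -0.27 (SE 0.30), the guidance receptor gene ROBO2 at 0.26 (SE 0.34) and HMGB1 at 0.22 (SE 0.30). Its median was -0.03, its mean 0.01 and its test upward, and leaving out TRIM9 replicate 1 gave 0.00747, also upward. No member passed over all genes or adjusted over the list alone (0 and 0) apart from BCL2L11. In the direct comparison these lists had adjusted p of 0.217 (median -0.05, mean 0.30) and 0.213. The first includes BCL2L11 with its plasmid reads, and without it had 0.996 (range over its alternatives 2.98e-04 to 0.996). The first passed without BCL2L11 replicate 1 (2.98e-04) or TRIM9 replicate 2 (0.00133), on the higher side and with BCL2L11 kept in the list, and the second on the lower side without BCL2L11 replicate 2 (0.00308) or TRIM9 replicate 1 (0.00523). Each list against the other trigger's comparison with GFP had adjusted p of 0.792 (miR-221/222 targets, TRIM9, and 0.0276 with the test pointing up without TRIM9 replicate 1) and 0.623 (miR-218 targets, BCL2L11).

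The host gene of miR-221 and miR-222, MIR222HG, stood at -0.01 (SE 0.30) with the BCL2L11 trigger and 0.55 (SE 0.30) with the TRIM9 trigger, and SLIT2, a host of miR-218, at 0.06 (SE 0.57) and 0.29 (SE 0.57). Both gave 0 calls over all genes and 0 adjusted over the list alone. Factors of the miRNA pathway (26 tested) had adjusted p of 0.392, 0.148 and 0.618 for BCL2L11, TRIM9 and their direct comparison, with ZSWIM8, the receptor of the ligase that degrades paired Argonaute, at 0.05 (SE 0.34) and -0.04 (SE 0.34) against GFP, chosen after its values were seen. This list passed on the lower side for BCL2L11 without GFP replicate 1 (0.044), for TRIM9 without GFP replicate 1 (0.00658) or TRIM9 replicate 2 (0.0128), and on the higher side in the direct comparison without BCL2L11 replicate 1 (0.00632) or TRIM9 replicate 2 (0.0215). In the TRIM9 comparison this list passed with a term for the library sets (lower, adjusted p = 0.0201, range over its alternatives 0.00658 to 0.987), with TENT2 at -0.63 (SE 0.46). Interferon response genes (10 tested) had adjusted p of 0.623, 0.792 and 0.815, with IFI27 at -0.78 (SE 0.26) for TRIM9. Cell cycle genes (26 tested) had 0.623, 0.586 and 0.967, with CDC6 at -0.60 (SE 0.29) for TRIM9. Cholesterol synthesis genes (17 tested) had 0.957, 0.314 and 0.157, with HMGCS1 at 0.33 (SE 0.42) for TRIM9, and passed in the direct comparison with a term for the library sets (lower, adjusted p = 0.0355, range over its alternatives 0.0355 to 0.912). The heat shock, unfolded protein response and p53 lists had 0.623 each for BCL2L11 against GFP. In the direct comparison immediate early genes had 0.897 and mitochondrially encoded genes 0.262. The BCL2 family list in the TRIM9 comparison had 0.792. In the direct comparison the medians of the immediate early (-0.13) and cell cycle (-0.04) lists were below 0 while their tests pointed up. All these lists gave 0 member calls over all genes and 0 adjusted over the list alone, and with a term for the library sets 1 immediate early gene passed over the list alone in the direct comparison.

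Few marker genes of other cell types passed the filter. Of 10 fibroblast genes 2 were tested, of which ACTA2 stood at 6.83 and 1.91 FPKM with the TRIM9 trigger against 14.7 and 14.6 (-1.71, SE 0.52, 1 call adjusted over the list alone and 0 over all genes) and COL1A1 at 0.46 (SE 0.38). Of the blood genes 3 were tested, CD14, HBA1 and ITGB2 (-0.72, 0.28 and 0.06 for TRIM9, list adjusted p = 0.586 for TRIM9, 0.987 for BCL2L11 and 0.359 in the direct comparison). Their median for TRIM9 was 0.06 while their mean was -0.12 and the test pointed down. Of the epithelial genes 1 was tested, EPCAM (-0.05 for TRIM9 and 0.15 for BCL2L11), with 0 calls over all genes or adjusted over the list alone. A term for the library sets gave 1 call over the list alone among the blood genes for TRIM9 and 1 among the fibroblast genes in the direct comparison.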

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

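All tests of explanations in this part were chosen only after the result was seen, and the comparison of BCL2L11 with TRIM9 cells was planned.

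A difference between the trigger groups, tested directly, singled out miR-221-3p (log2 fold change -1.38), BCL2L11 (10.88) and TRIM9 (-10.73) in BCL2L11 against TRIM9 cells. It also singled out the medians of the heat shock (0.28), p53 target (0.39), histone (0.43), unfolded protein response (0.16) and BCL2 family (0.0856) lists, none of which passed with an estimated correlation. In simulation camera with that setting recovered 0 of 20 lists of independent genes lowered by 0.5. Not passing with it therefore does not argue against a list of nearly independent genes. The simulation cannot decide this for correlated genes, and the estimated correlation of the histone list was 0.15.

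Heat shock genes were lower with the TRIM9 trigger than with GFP, led by HSPA6, DNAJB1 and BAG3, though the list did not pass with an estimated correlation (adjusted p = 0.103). Reads divided among near-identical copies are argued against by the sum over all HSPA1A and HSPA1B loci, which stood at -1.15 (SE 0.40). Scaling of the libraries would shift all genes of a library nearly alike, and so would not set the list apart. The median of the list was -0.36 against -0.04 for the other genes, which argues against scaling as the source of that gap. Rescaling by TMM also shifts all genes nearly alike. The median after it, -0.29 against 0.02 for all genes, is therefore no further test. Each library set held a library of each group, so a shift shared within a set cancels in this comparison. The smaller of the within-set differences from all genes, -0.18, shows only that the list was lower in both sets. Less plasmid stress or a different transfection reagent in these dishes could give the same values and were not tested, nor was an effect of TRIM9 RNA.

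RAB4B-EGLN2 and AC025165.3 stood higher with the TRIM9 trigger (adjusted p = 0.122 each, passing only in some alternatives), yet the summed FPKM of the genes that overlap each on its strand differed from GFP by 0.12 (SE 0.47) and 0.11 (SE 0.31) on the log2 scale. A candidate explanation is that reads were assigned to other overlapping gene models. EGLN2 and TSFM are among the overlapping genes. No biological explanation was tested.

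Histone genes were lower with the TRIM9 trigger in both library sets, the smaller difference from all genes being -0.64. A shift shared within a set cancels in this comparison, so these values do not test a difference between sets. The list did not pass with an estimated correlation (camera, adjusted p = 0.103). Less carry-over of RNA without a poly-A tail may contribute: the median of 6 such RNAs was -1.21, with RN7SK at -3.33 and RMRP at -2.30 but RN7SL2 at 0.74 (SE 1.24). Fewer cells in S phase was left open, as the median of 9 S phase genes was -0.20 against -0.04 for all genes, with a SE of 0.28 to 0.66 for each gene, and the cell cycle list did not pass (adjusted p = 0.586).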

How the results depend on the processing

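The list tests with TMM, the library sets, without each library and without BCL2L11, and the fit on assembled chromosomes, were chosen only after the results were seen. A library left alone in its group is assumed to vary like the other groups. Sign changes of values that passed in neither setting were not counted as reversals. The cause was not tested for any change below, except where BCL2L11 itself was left out.

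Of 2720 alternatives for 198 gene fold changes 2703 kept their side of the threshold and 17 passed newly. Of 692 for 54 miRNA fold changes 671 kept it, 13 no longer passed and 8 passed newly. Of 384 for 42 gene list results 322 kept it, 46 no longer passed, 14 passed newly and 2 reversed. Of 81 counts of calls 58 stayed within 1.5 times and 23 moved. Among genes only BCL2L11 and TRIM9 passed in the main fits, so most gene fold changes that kept their side passed in neither setting. Among miRNAs only miR-221-3p passed in the main fits, for BCL2L11 against GFP and against TRIM9. All 13 miRNA results that no longer passed lie among its 14 and 13 alternatives there. Likewise the 46 list results that no longer passed come only from lists that passed in the main tests. The numbers that kept their side therefore do not show that those results were stable.

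For BCL2L11 against GFP the 1 miRNA call became 0 with total counts, 0 with only the compared groups and 5 with the library sets, and 0 without any 1 of the 6 libraries. miR-221-3p stood at -1.25 with total counts, -1.16 with the compared groups and -1.22 to -1.07 without 1 library, and miR-222-3p at -0.60 with the library sets, where it passed. For TRIM9 against GFP no filter gave 1 call. In BCL2L11 against TRIM9 cells the 1 call became 0 with total counts, 4 with no filter, 3 with DESeq2, 0 with the compared groups and 4 with the library sets, and 0 to 2 without 1 library. The 1 gene call of TRIM9 against GFP became 5 with the compared groups and 6 with the library sets, and 1 to 5 without 1 library.

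With an estimated correlation the adjusted p for BCL2L11 against GFP was 0.876 (BCL2 family) and 0.903 (immediate early, mitochondrial and histone genes). For TRIM9 against GFP it was 0.103 (heat shock, p53 targets, histones), 0.218 (unfolded protein response) and 0.590 (mitochondrial genes). For BCL2L11 against TRIM9 it was 0.0795 (heat shock), 0.103 (p53 targets) and 0.135 (histones, unfolded protein response, BCL2 family). With the library sets it was 0.0688 (BCL2 family, histones) and 0.103 (immediate early genes) for BCL2L11 against GFP, 0.0201 (miRNA pathway) for TRIM9 against GFP and 0.0355 (cholesterol synthesis) for BCL2L11 against TRIM9. With TMM it was 0.0530 (immediate early genes) and 0.0534 (mitochondrial genes) for BCL2L11 against GFP. Without BCL2L11 the BCL2 family list had 0.549 against GFP and 0.213 against TRIM9.

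Without 1 library the adjusted p for BCL2L11 against GFP ranged from 1.07e-04 to 0.674 (miR-221/222 targets), 0.0440 to 0.716 (miRNA pathway), 0.0275 to 0.127 (BCL2 family), 9.40e-06 to 0.631 (immediate early genes, reversed at 0.631 without GFP replicate 2), 0.00847 to 0.815 (mitochondrial genes) and 1.07e-04 to 0.847 (histones). For TRIM9 against GFP it ranged from 0.0276 (reversed, without TRIM9 replicate 1) to 0.700 (miR-221/222 targets), 0.00747 to 0.859 (miR-218 targets), 0.00658 to 0.987 (miRNA pathway), 0.0216 to 0.305 (unfolded protein response), 1.01e-04 to 0.443 (immediate early genes) and 0.00106 to 0.305 (mitochondrial genes). For BCL2L11 against TRIM9 it ranged from 2.98e-04 to 0.546 (miR-221/222 targets), 0.00308 to 0.377 (miR-218 targets), 0.00632 to 0.619 (miRNA pathway), 0.0118 to 0.304 (unfolded protein response), 0.00236 to 0.0668 (BCL2 family) and 2.01e-07 to 0.0866 (histones).

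The seed site results were not run, as no genome was used, and neither were isoforms per library. With 2 libraries per group a 1.5-fold change of a miRNA was recovered in 5% and 25% of simulated cases, which limits what 0 calls can show. These cases covered only the more abundant miRNAs.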

Other observations

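The strand ratio of miR-221, the difference between its strands and the comparison with transcript length were chosen only after the result was seen, while the term for the library sets and the naming of miR-221-5p and MIR222HG were planned.

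Loss of miR-221-3p without loss of its partner strand may reflect decay of the mature strand, as a hypothesis. If the whole miR-221 hairpin had been made less, miR-221-5p would have fallen as much, yet its log2 fold change with the BCL2L11 trigger stood above that of miR-221-3p by 1.10 (SE 0.22). This SE combined those of the strands as if independent, though both strands were counted in the same libraries. The ratio of miR-221-3p to miR-221-5p was 2.61 and 2.53 with the BCL2L11 trigger against 5.00 and 6.06 in GFP cells. MIR222HG, the host transcript, stood at -0.01 (SE 0.30). A lower rate of hairpin production with slower decay of miR-221-5p was not tested.

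Some small RNAs of other tissues varied between libraries of 1 group. miR-451a, a miRNA of red blood cells, had 11431 and 12877 reads in GFP, 2324 and 11951 in BCL2L11 and 5558 and 11386 in TRIM9 cells, and miR-486-5p had 715 and 713, 352 and 739, and 444 and 672. miR-150-5p, a miRNA of lymphocytes, had 158 reads in TRIM9 replicate 1 and 0 to 2 in the other 5 libraries.

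Gene levels differed between library sets in a similar way in each group, with correlations of 0.49 to 0.83 between the groups' deviations from their means. With a term for the sets 4991 of 15183 genes passed in limma, 3421 higher and 1570 lower in set 2. Across genes, which are not independent replicates, the difference between sets rose with transcript length, with a Spearman correlation of at least 0.45 in each group. Genes of up to 1279 nt had medians of -0.22, -0.50 and -0.49 in GFP, BCL2L11 and TRIM9 cells and those of at least 4558 nt 0.53, 0.62 and 0.62. RNA integrity or fragment length that differed between preparations is a candidate explanation, which the correlation of 0.45 fits but which was not measured. In the small RNA libraries 56 of 443 miRNAs passed for the sets, but the groups were less alike, with correlations of 0.21 to 0.39. Among those that passed, miR-451a stood at 2077 and 2297 CPM in GFP cells but at 432 and 2134 with the BCL2L11 trigger.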
